A study of Homo sapiens and Mus musculus with 57 samples.

How the data were processed

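RNA-seq was measured in 57 libraries of 8 tumour cell lines, in 19 groups of 3 libraries, after 16 h with DMSO, TAK-981 or ML-792 (each inhibitor at 1 uM). Per the labels' protocols, RNA was taken from the cells with RNeasy columns, libraries were made with a TruSeq RNA kit from poly(A) RNA, and paired-end reads were sequenced on a NovaSeq instrument. The aligner, the counting tool, the genome build, the annotation and whether counting used strand are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart. Per the file headers, each deposited file held an expected count and an FPKM value per gene. The estimated counts deposited by the authors were not normalized and not always whole: genes with fractional values held 11.2 to 33.9% of the counts of a library. The FPKM values of the authors, scaled by gene length and by the fragments of the library, were used in an alternative only.

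Samples were grouped by line and treatment as the labels name them. The labels describe wells seeded in triplets and do not say that these were separate cultures, so p-values measure only the spread between these samples, which may be technical. All 57 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom from 2.18 to 22.6), and 0 pairs held identical values. Totals ran from 15296175 to 25807864 counts per library, and no row without a gene name was found. Human tables listed 30373 rows by symbol, of which 19498 matched a current gene symbol, 37 were Ensembl identifiers and 1354 were numbered copies of a symbol. Mouse tables listed 43432 Ensembl identifiers, of which 0 matched the name tables used here, so mouse genes are given by identifier and mouse gene lists were not tested.

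Expected counts were rounded to whole numbers. Each line was fitted by itself in edgeR 4.0.16 (R 4.3.3) with filterByExpr (count minimum 10, total minimum 15), TMM scaling and the quasi-likelihood F-test. Groups of the 3 lines with both inhibitors shared one estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a call of at least 1 on the log2 scale was counted as 2-fold. Fold changes are log2 values with standard errors, and CPM values are means over libraries scaled by TMM. Intervals are at the 95% level. The 2 compounds were compared directly within each line. Agreement of compounds that share DMSO libraries was set beside 20 simulated datasets with unchanged groups and beside the overlap of independent lists. Every library of a line, DMSO included, was simulated there from the DMSO means, each gene by itself. Differences between lines were tested as the interaction of TAK-981 with line, by species, with each pair of lines as a contrast.

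Tests, samples, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison of TAK-981 with DMSO, up to 10 rises and 10 falls of the largest log2 fold change among called genes with at least 5 CPM in the higher group and no overlap between the groups. For ML-792 and between the compounds it took up to 5 each way. It also took up to 4 members of each gene list with the smallest adjusted p, the genes of the target enzyme (UBA2 and SAE1) in every line, up to 10 genes called alike in all lines of a species and up to 10 with the smallest adjusted p for a difference between lines. Predicted or clone-named genes could be skipped in favour of the next gene, and some genes the rule names are not reported here. Values of genes outside the rule are named as chosen after their values were seen.

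The 23 gene lists held 557 memberships, all of which matched a row by current or older symbol. Lists with at least 3 measured genes were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. The second test uses only the few residual degrees of freedom of a line, fewest in THP-1 among the human lines. A call lost with it therefore does not show that a list was unchanged, and lost calls do not rank the lines. Of 220 tests 63 were called with the preset correlation. The signs of the median, the mean and the test differed for 1 called list, the epithelial markers with ML-792 in MDA-MB-231, and for 28 lists that were not called.

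HCT116, Colo205 and MDA-MB-231 carry shared replicate numbers in their labels, and a fit with the number as a block was planned as an alternative. In Colo205 all 9 pairs of libraries with the same number deviated together, with correlations of their deviations from the group means of 0.106 to 0.448, above the threshold of 0.1. The blocked value is therefore given for Colo205 where it changed a call. In MDA-MB-231 the 3 pairs of DMSO with TAK-981 were also over it (0.326, 0.35 and 0.133), but not all pairs with ML-792. There the block changed no list call of TAK-981 against DMSO and moved no count of that comparison by over 1.5 times. Other alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of the 2 groups alone, a fit over all lines of a species, a fry test, genes of at least 10 CPM for the agreement of compounds, and leaving out each library in turn. Alternatives chosen after seeing the data were limma on log2(FPKM + 1), a fit without the 37 mitochondrial genes, 2-fold calls among genes of at least 10 CPM, and the differences between human lines without 1 of the lines. Gene names and neighbours came from a RefSeq table of GRCh38.p14, lengths and GC content from the longest transcript of each gene in GENCODE 29, and no coordinates are given. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

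The scripts were tested on simulated data with 200 changed genes per comparison, drawn from the real means and library sizes, with 0 wrong signs in every comparison. In THP-1 80% of 1.5-fold and 94% of 2-fold changes were recovered. In HCT116 these shares were 76% and 88% for TAK-981, 76% and 90% for ML-792, and 80% and 92% between the compounds. In Colo205 they were 79% and 90%, 75% and 98%, and 77% and 95%, and in MDA-MB-231 89% and 90%, 90% and 95%, and 91% and 95%. In the mouse lines they were 76% and 94% in CT26, 79% and 96% in MC38, 86% and 98% in B16F10, and 74% and 94% in A20. From 9 to 20 unchanged genes were called per comparison. For differences between lines, 95% of 2-fold differences were recovered in human lines (17363 genes) and 94.5% in mouse lines (15332 genes), with 8 and 6 unchanged genes called. In the simulated data few genes changed, with as many rises as falls. They therefore do not test scaling or recovery where much of the transcriptome changes, as in THP-1, where 69.4% of genes were called.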

Results

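RNA was sequenced from 8 tumour cell lines that were kept for 16 h with the vehicle DMSO or with 1 uM of an inhibitor of the SUMO-activating enzyme, the SAE1 and UBA2 heterodimer that starts the conjugation of SUMO proteins to other proteins. The human lines were THP-1 (monocytic leukaemia), HCT116 and Colo205 (colorectal carcinoma) and MDA-MB-231 (breast carcinoma). The mouse lines were CT26 and MC38 (colon carcinoma), B16F10 (melanoma) and A20 (B cell lymphoma). All 8 lines received TAK-981, and HCT116, Colo205 and MDA-MB-231 also received a second inhibitor, ML-792. The 57 libraries formed 19 groups of 3. Human libraries held 17336368 to 25807864 estimated counts and mouse libraries 15296175 to 24216296, and 15741 to 18375 genes were detected per library. The comparisons addressed how large the transcriptional response was in each line, which genes it involved, and how the compounds compared with each other.

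**Figure D1:**
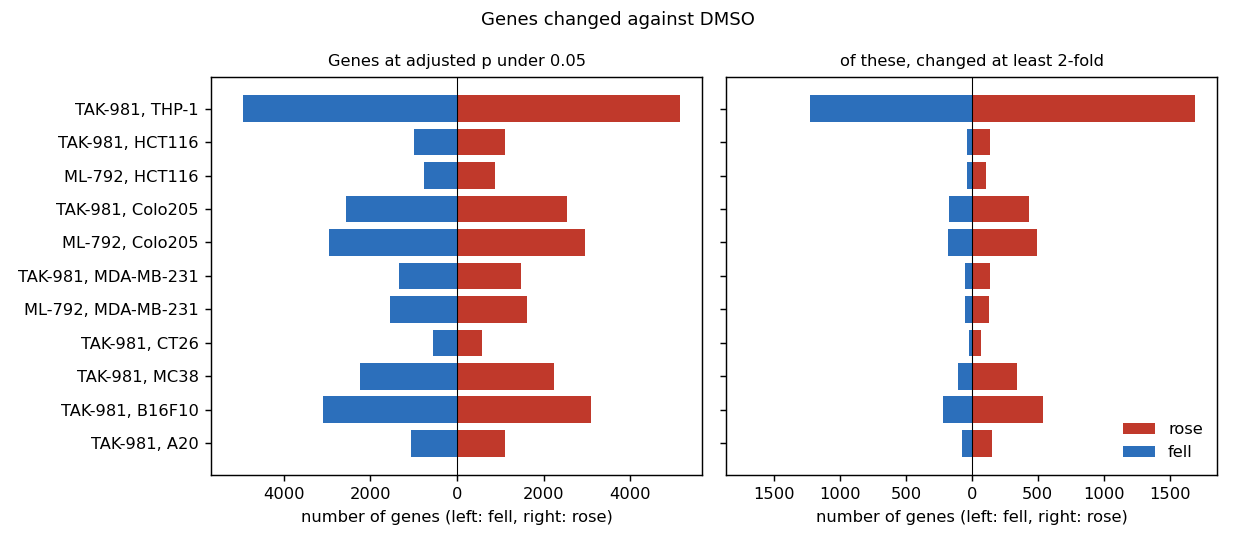
Number of genes that rose (bars to the right) or fell (to the left) in each comparison of an inhibitor with DMSO, on the left at an adjusted p under 0.05 (edgeR, 3 libraries against 3) and on the right those that also changed at least 2-fold. In the left panel THP-1 had 5150 rises and 4924 falls with TAK-981, and CT26 had 578 and 559.

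In THP-1 cells most interferon-stimulated genes rose and most genes of cholesterol synthesis fell with TAK-981. Both lists were called with the preset correlation and not with an estimated one, which leaves few degrees of freedom here (adjusted p = 0.225 and 0.388 with an estimated correlation). The mitochondrial genes took 15.5 ± 1.75% of counts against 7.38 ± 0.215% in DMSO (SD, n = 3). IFI44L rose by 5.31 on the log2 scale (SE 0.266, n = 3 per group) and IFIT1, an interferon-induced RNA-binding protein, by 4.80 (SE 0.21). MS4A3, a membrane protein of granulocyte and monocyte precursors, fell by 3.64 (SE 0.108), from 345 ± 27.3 to 27.6 ± 4.64 CPM. In all, 5150 genes rose and 4924 fell among 14526 tested, which was 69.4% of them, and 1694 rises and 1230 falls were 2-fold or larger. The median size of a called change was 0.684. Among genes with a mean of at least 10 CPM, 1430 changed 2-fold or more, and rises made up 36.7% of these against 57.9% without that limit.

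IRF9, the DNA-binding subunit of the interferon-activated factor ISGF3, rose by 5.71 in THP-1 (SE 0.951), from 0.237 ± 0.41 CPM to 12.5 ± 9.51 CPM (SD, n = 3), but single libraries set the size of this rise. DMSO libraries held 0 to 0.71 CPM and TAK-981 libraries 1.675 to 19.4 CPM. The rise was 5.10 without DMSO replicate 5 and 5.12 without DMSO replicate 6, and without DMSO replicate 4 the other DMSO libraries held 0, so no fold was given. Among the other large rises in THP-1 were MDGA1 (5.62, SE 0.19), NGFR, the nerve growth factor receptor (4.62, SE 0.192), ZNF280A (4.29, SE 0.153), PPAP2C (4.19, SE 0.235), ADAM28 (4.13, SE 0.265) and VASN (3.89, SE 0.21). REXO1L1 rose by 5.57 (SE 0.109), which is uncertain because its reads can be shared with near-identical copies of the gene. UGT3A2, a glycosyltransferase, fell by 5.14 (SE 0.175). Large falls were also measured for CAV1, the caveolae coat protein (-3.70, SE 0.157), the protease inhibitor SERPINB2 (-3.55, SE 0.0851), PLAC8 (-3.31, SE 0.108), GPR160 (-3.30, SE 0.122), the prolactin receptor PRLR (-3.26, SE 0.186), RUFY4 (-2.84, SE 0.166) and DNPH1 (-2.83, SE 0.0775). MT1G fell by 3.47 (SE 0.129), uncertain because metallothionein genes have similar sequences. The genes of the target enzyme itself fell less, UBA2 by 0.41 (SE 0.0851) and SAE1 by 0.68 (SE 0.0685).

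Of 42 measured interferon-stimulated genes in THP-1, 39 rose, 2 fell and 1 was not called (camera adjusted p = 4.56e-11; adjusted p = 0.225 with an estimated correlation). MX1 rose by 3.78, IFIT2 by 3.56, OAS3 by 2.68 and OAS2 by 2.66. Of 21 NF-kB and inflammation genes, 17 rose and 1 fell (adjusted p = 3.62e-06; adjusted p = 0.109 with an estimated correlation), among them BCL3 (2.91), TNFAIP2 (2.66) and NFKBIA, the inhibitor of NF-kB (2.04). Of 27 p53 target genes, 17 rose and 6 fell (adjusted p = 0.00638; adjusted p = 0.23 with an estimated correlation), with rises of 2.44 for BTG2, 2.26 for the cell cycle inhibitor CDKN1A, 1.91 for PLK2 and 1.57 for SESN1. All of these rises were measured in libraries in which the mitochondrial genes took 15.5 ± 1.75% of counts, against 7.38 ± 0.215% in the DMSO libraries (SD, n = 3).

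The lists that moved down in THP-1 were measured in the same libraries. Large falls were common there among well-expressed genes: rises made up 36.7% of 2-fold calls with a mean of at least 10 CPM. The list test was not matched on the level of expression, so it cannot part these falls from that trend. Of 24 genes of cholesterol synthesis and its control, 0 rose and 23 fell (adjusted p = 6.78e-07; adjusted p = 0.388 with an estimated correlation), including INSIG1 (-1.33) and the transcription factor SREBF2 (-1.12). Of 30 ribosome biogenesis and MYC-linked genes, 3 rose and 23 fell (adjusted p = 0.000214; adjusted p = 0.235 with an estimated correlation), with NPM1, a nucleolar protein, at -1.73 and MYC at -1.02. Of 34 mitosis genes, 3 rose and 21 fell (adjusted p = 0.00237; adjusted p = 0.464 with an estimated correlation), among them BIRC5 (-1.22), UBE2C (-1.09) and CCNB2 (-1.003). Of 20 NRF2 and antioxidant genes, 3 rose and 13 fell (adjusted p = 0.0432; adjusted p = 0.613 with an estimated correlation). FTL, the ferritin light chain, fell by 1.90 and PRDX1 by 1.39, while OSGIN1 rose by 3.24. Adjusted over the list alone, the counts of the 7 called lists in THP-1 were the same as over all genes.

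The remaining lists were not called in THP-1, although many of their members were. Of 8 interferons and chemokines, 5 rose and 1 fell (adjusted p = 0.273): CCL2 rose by 3.04 and CCL3 by 2.98, and CCL5 fell by 1.84. Of 22 genes of antigen presentation by MHC class I, 6 rose and 13 fell (adjusted p = 0.0935), with IRF1 at 1.79 and the chaperone CALR at -2.09. Heat shock genes (5 rose and 12 fell of 19, adjusted p = 0.0535), genes of the unfolded protein response of the endoplasmic reticulum (6 and 10 of 20, adjusted p = 0.0628), replication genes (8 and 15 of 34, adjusted p = 0.278) and ATF4 and CHOP stress genes (8 and 13 of 24, adjusted p = 0.409) went both ways. So did hypoxia and glycolysis genes (7 and 9 of 20, adjusted p = 0.974), BCL2 family genes (9 and 5 of 15, adjusted p = 0.353) and SUMO pathway genes (11 and 8 of 27, adjusted p = 0.927). In the SUMO pathway list, SUMO2 fell by 1.33 and the ubiquitin ligase RNF111 rose by 1.31.

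Markers of cell types were also measured in THP-1. Of 22 myeloid markers, 10 rose and 8 fell (adjusted p = 0.927): ELANE, neutrophil elastase, and LYZ, lysozyme, fell by 1.46 and 1.83. Of 10 B cell markers 6 rose and 2 fell (adjusted p = 0.251), of 15 mesenchymal markers 8 rose and 5 fell (adjusted p = 0.512), of 5 melanocyte markers 2 rose and 1 fell (adjusted p = 0.945), and of 7 epithelial markers 2 rose and 0 fell (adjusted p = 0.704). Of 12 germline genes 2 rose and 5 fell (adjusted p = 0.457), and adjusted over the list alone 4 fell. For the melanocyte markers 3 rose and 2 fell when adjusted over the list alone. Only 2 cleavage-stage genes were measured, too few for a list test, of which ZNF280A was the one that rose.

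**Figure D2:**
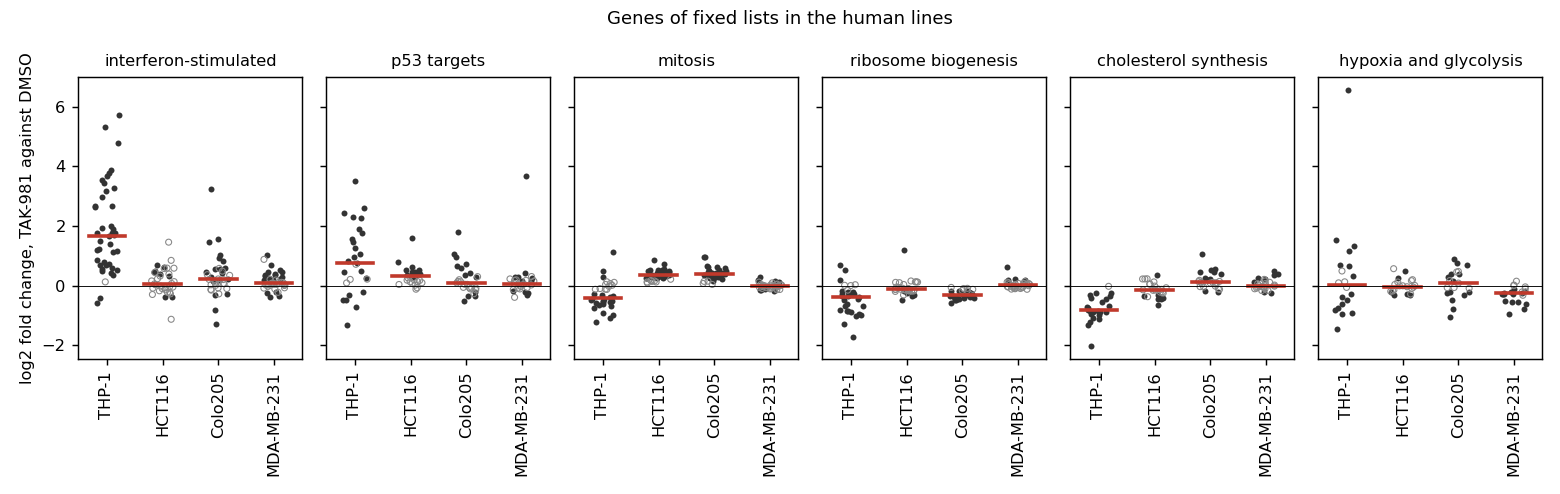
Log2 fold change of each measured gene of 6 lists with TAK-981 against DMSO in the 4 human lines (filled points, adjusted p under 0.05; open points, not called; red lines, median of the list). Interferon-stimulated genes had a median of 1.67 in THP-1, and mitosis genes a median of 0.39 in Colo205.

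In HCT116 cells p53 targets rose with both inhibitors (adjusted p = 0.0222 for TAK-981 and 0.0198 for ML-792 with an estimated correlation). Most mitosis genes rose too, but that list was called only with the preset correlation (adjusted p = 0.109 and 0.0931 with an estimated correlation). ACTL8, an actin-like gene, rose by 4.84 with TAK-981 (SE 0.241) and 4.85 with ML-792 (SE 0.241), from 0.319 ± 0.213 to 9.43 ± 0.663 and 9.49 ± 0.0506 CPM (SD, n = 3), and by 5.52 and 5.53 without DMSO replicate 3. DHRS2, a short-chain dehydrogenase, rose by 4.195 (SE 0.112) and 4.07 (SE 0.112), and H19, an imprinted noncoding RNA, by 3.20 (SE 0.111) and 3.12 (SE 0.112). TAK-981 raised 1118 genes and lowered 980 of 14574 tested, of which 139 rises and 36 falls were 2-fold or larger. With ML-792 875 rose and 768 fell, and 109 and 34 of these were 2-fold or larger. Median sizes of the called changes were 0.399 and 0.437. TAK-981 replicate 1 stood apart on the second principal component, at -35.5 against -5.9 and 0.7 for the other TAK-981 libraries. Without 1 library, the total of 2098 for TAK-981 fell to 1374 (DMSO replicate 1) and 1281 (DMSO replicate 2), and the total of 1643 for ML-792 to 944 (DMSO replicate 2), 1032 (DMSO replicate 3) and 1064, 768 and 874 (ML-792 replicates 1, 2 and 3).

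Further rises with TAK-981 in HCT116 were measured for ASMTL (2.82, SE 0.0885), LINC00085 (2.44, SE 0.212), C20orf112 (2.31, SE 0.106), ZSCAN31 (2.13, SE 0.114), the cytokine receptor CSF2RA (1.75, SE 0.158), SHANK3 (1.69, SE 0.115) and GDF15 (1.61, SE 0.11). With ML-792 ASMTL rose by 2.75 (SE 0.0883) and C20orf112 by 2.16 (SE 0.106). KIAA1199 fell by 2.11 with TAK-981 (SE 0.22) and by 1.67 with ML-792 (SE 0.213), and the metalloprotease ADAM19 fell by 1.81 (SE 0.113) and fell by 1.498 (SE 0.111). PADI3 (-1.47, SE 0.179), the retinaldehyde-oxidising enzyme ALDH1A3 (-1.34, SE 0.0602), SEMA3D (-1.25, SE 0.183), HAS3 (-1.20, SE 0.0816), the WNT antagonist DKK1 (-1.19, SE 0.0694), ZBED2 (-1.09, SE 0.0836), CPA4 (-1.08, SE 0.0887) and DBNDD1 (-1.06, SE 0.0863) fell with TAK-981. PADI3 fell by 1.56 (SE 0.181) and ALDH1A3 by 1.30 (SE 0.0602) with ML-792. The read-through transcript NDUFC2-KCTD14 was listed at -2.78 with ML-792 (SE 0.499), which is uncertain because it overlaps other genes.

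Of 34 mitosis genes, TAK-981 raised 27 and ML-792 28 in HCT116, and 0 fell (adjusted p = 1.25e-18 and 1.87e-23; adjusted p = 0.109 and 0.0931 with an estimated correlation). CENPA, the centromeric histone, rose by 0.85 with TAK-981, KIF20A by 0.72, PLK1 by 0.53 and NEK2 by 0.51. Of 27 p53 targets, 15 rose with TAK-981 and 10 with ML-792, and 0 fell (adjusted p = 5.33e-09 and 2.92e-10). These calls held with an estimated correlation (adjusted p = 0.0222 and 0.0198). BBC3, a pro-apoptotic BCL2 family gene, rose by 0.79, CDKN1A by 0.62 and PLK2 by 0.45 with TAK-981. Adjusted over the list alone, 30 and 31 mitosis genes and 16 and 18 p53 targets rose.

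Among the other lists called upward with TAK-981 in HCT116 were ATF4 and CHOP stress genes (8 rose and 0 fell of 23, adjusted p = 1.87e-06; adjusted p = 0.504 with an estimated correlation), with DDIT3, which encodes CHOP, at 1.24 and CEBPB at 0.81. For NF-kB genes 7 rose and 0 fell of 20 (adjusted p = 0.000734; adjusted p = 0.388 with an estimated correlation), with RELB at 0.74 and NFKB2 at 0.60. For the unfolded protein response 8 rose and 0 fell of 20 (adjusted p = 0.00152; adjusted p = 0.23 with an estimated correlation), with XBP1 at 0.44 and CRELD2 at 0.48. For MHC class I presentation 7 rose and 1 fell of 21 (adjusted p = 0.0228; adjusted p = 0.464 with an estimated correlation), with HLA-B at 0.76, uncertain because HLA genes share reads. Downward calls were made for replication genes (1 rose and 11 fell of 34, adjusted p = 0.00112; adjusted p = 0.347 with an estimated correlation), where MCM6 fell by 0.53 and RRM2 rose by 0.92. They were also made for cholesterol genes (1 and 6 of 25, adjusted p = 0.0219; adjusted p = 0.536 with an estimated correlation) and ribosome biogenesis genes (1 and 5 of 30, adjusted p = 0.0241; adjusted p = 0.388 with an estimated correlation), where MYC fell by 0.36 and ODC1 rose by 1.19. Adjusted over the list alone, 16 replication genes fell and 3 rose.

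With ML-792 in HCT116, ATF4 and CHOP stress genes (5 rose and 0 fell of 23, adjusted p = 3.22e-05; adjusted p = 0.536 with an estimated correlation), NF-kB genes (4 and 1 of 20, adjusted p = 0.00918; adjusted p = 0.472 with an estimated correlation), the unfolded protein response (8 and 0 of 20, adjusted p = 2.1e-06; adjusted p = 0.109 with an estimated correlation) and MHC class I presentation (8 and 1 of 21, adjusted p = 0.0191; adjusted p = 0.464 with an estimated correlation) were called upward. Heat shock genes were called upward with ML-792 (6 and 1 of 19, adjusted p = 0.0217; adjusted p = 0.496 with an estimated correlation) and not with TAK-981 (4 and 2, adjusted p = 0.139). Replication genes (2 and 10 of 34, adjusted p = 0.0033; adjusted p = 0.383 with an estimated correlation) and ribosome biogenesis genes (1 and 6 of 30, adjusted p = 0.00308; adjusted p = 0.262 with an estimated correlation) were called downward. Cholesterol genes were not called with ML-792 (1 and 2 of 25, median 0.007, adjusted p = 0.927).

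In Colo205 cells most mitosis genes rose and most ribosome biogenesis genes fell with both inhibitors. These calls were lost with an estimated correlation (adjusted p = 0.133 and 0.175 for mitosis and 0.0832 and 0.109 for ribosome biogenesis with an estimated correlation). OPRK1, the kappa opioid receptor, rose by 6.72 with TAK-981 (SE 0.314) and 6.61 with ML-792 (SE 0.318), from 0.0811 ± 0.0285 to 9.13 ± 2.07 and 8.53 ± 0.417 CPM (SD, n = 3). ENTPD8, an ectonucleotidase, rose by 6.53 (SE 0.118) and 6.59 (SE 0.118), from 1.01 ± 0.205 to 93.6 ± 8.09 and 97.3 ± 4.54 CPM. CREB3L3, a transcription factor of liver and intestine, rose by 5.62 (SE 0.209) and 5.56 (SE 0.21), or 6.28 and 6.22 without DMSO replicate 1, and PDK4, a pyruvate dehydrogenase kinase, by 4.60 (SE 0.145) and 4.57 (SE 0.146). TAK-981 raised 2538 genes and lowered 2554 of 14174 tested, with 436 rises and 172 falls of 2-fold or more. With ML-792 2966 rose and 2949 fell, with 497 and 180 of 2-fold or more.

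ADIRF (5.01, SE 0.137), the phospholipase PNPLA7 (4.35, SE 0.127), DHRS2 (3.997, SE 0.188), NEURL1B (3.68, SE 0.152), RHOBTB1 (3.66, SE 0.25) and NSMF (3.46, SE 0.069) also rose with TAK-981 in Colo205. PTGIS, prostacyclin synthase, fell by 3.03 with TAK-981 (SE 0.213) and by 2.83 with ML-792 (SE 0.21). The calcium channel subunit CACNA1E fell by 2.33 (SE 0.0757) and 2.19 (SE 0.075), ADAM19 by 2.24 (SE 0.0705) and 2.06 (SE 0.0697), and UNC93A by 1.97 (SE 0.124) and 2.29 (SE 0.129). With TAK-981 PRR9 (-2.34, SE 0.19), the dynein gene DNAH9 (-2.12, SE 0.175), HMOX1, which encodes an inducible heme oxygenase (-1.99, SE 0.123), MYH4 (-1.92, SE 0.226), the transcription factors RUNX3 (-1.90, SE 0.133) and SPDEF (-1.90, SE 0.135) fell too. SPRR2D fell by 2.07 with ML-792 (SE 0.401) and fell by 2.90 without ML-792 replicate 2, uncertain because the SPRR2 genes are close copies.

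Of 34 mitosis genes in Colo205, TAK-981 raised 30 and ML-792 28, and 0 fell (adjusted p = 5.81e-15 and 1.53e-12; adjusted p = 0.133 and 0.175 with an estimated correlation). KIF20A rose by 0.97 with TAK-981, CENPA by 0.95, ANLN by 0.67 and CENPE by 0.63. Of 30 ribosome biogenesis genes, 24 fell and 0 rose with each compound (adjusted p = 3.32e-11 and 5.33e-09; adjusted p = 0.0832 and 0.109 with an estimated correlation), with DKC1 at -0.57 and NOLC1 at -0.45 with TAK-981. For MHC class I presentation 17 and 19 of 22 rose and 0 fell (adjusted p = 2.36e-07 and 3.27e-07; adjusted p = 0.12 with an estimated correlation for both), including ERAP2 (0.57) and B2M (0.47). For the unfolded protein response 17 of 20 rose with each compound, and 0 and 2 fell (adjusted p = 3.38e-07 and 3.06e-07; adjusted p = 0.383 with an estimated correlation for both), including HSPA5, the main chaperone of the endoplasmic reticulum (0.64). Adjusted over the list alone, 31 and 28 mitosis genes rose and 25 ribosome biogenesis genes fell with each compound.

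Of 37 interferon-stimulated genes in Colo205, 15 rose and 4 fell with TAK-981 and 14 and 6 with ML-792 (adjusted p = 0.00465 and 0.0241; adjusted p = 0.464 and 0.517 with an estimated correlation). CMPK2 rose by 3.26, OAS1 by 1.57 and IFI6 by 0.92 with TAK-981. Of 25 cholesterol genes, 9 rose, 2 fell and 14 were not called with TAK-981, and 14 rose and 0 fell with ML-792 (adjusted p = 0.0345 and 0.000523; adjusted p = 0.731 and 0.589 with an estimated correlation), with INSIG1 at 1.04 and HMGCS1 at 0.57 with TAK-981. ATF4 and CHOP stress genes were called downward with ML-792, where 5 of 23 rose and 16 fell (adjusted p = 0.0192; adjusted p = 0.623 with an estimated correlation). With TAK-981 5 rose and 7 fell and the list was not called (adjusted p = 0.647), and DDIT3 rose by 1.15 and DDIT4 fell by 1.11. In this line SUMO3 rose by 0.78 and SUMO2 by 0.65 with TAK-981, within a SUMO pathway list that was not called (8 rose and 3 fell of 27, adjusted p = 0.261). The epithelial marker KRT20 rose by 1.94 and the intestinal transcription factor CDX2 by 2.47 with TAK-981, within a list that was not called (7 rose and 2 fell of 20, adjusted p = 0.2).

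In MDA-MB-231 cells hypoxia and glycolysis genes fell with both inhibitors (adjusted p = 0.0198 for both with an estimated correlation). Most NF-kB and inflammation genes rose, but that call was lost with an estimated correlation (adjusted p = 0.383 and 0.464 with an estimated correlation). GDF15, a cytokine of the TGF-beta family, rose by 3.69 with TAK-981 (SE 0.117) and 3.29 with ML-792 (SE 0.12), from 1.58 ± 0.359 to 20.4 ± 0.96 and 15.4 ± 0.624 CPM (SD, n = 3). CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 3.20 (SE 0.118) and 3.36 (SE 0.115), the cytokine IL11 by 2.28 (SE 0.0432) and 2.29 (SE 0.0431), and TNFAIP2 by 2.04 (SE 0.0598) and 2.06 (SE 0.0598). TAK-981 raised 1488 genes and lowered 1330 of 13976 tested, with 135 rises and 49 falls of 2-fold or more. With ML-792 1624 rose and 1540 fell, with 131 and 50 of 2-fold or more. The median called change was 0.287 with TAK-981 and 0.271 with ML-792.

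Other rises with TAK-981 in MDA-MB-231 were TMEM71 (1.99, SE 0.0792), the decoy receptor TNFRSF11B (1.99, SE 0.0881), the zinc-finger genes ZNF699 (1.81, SE 0.115) and ZNF45 (1.72, SE 0.0499), FAM210A (1.72, SE 0.0586) and ANGPTL4 (1.70, SE 0.138). ALPP rose by 2.02 with ML-792 (SE 0.338), uncertain because placental-type alkaline phosphatase genes are near copies. C1orf110 fell by 1.40 with TAK-981 (SE 0.084) and by 1.25 with ML-792 (SE 0.0813), CLDN2 by 1.28 (SE 0.113) and 1.18 (SE 0.109), ARTN by 1.27 (SE 0.123) and 1.37 (SE 0.123), and GGT5 by 1.13 (SE 0.0895) and 1.15 (SE 0.0884). RGS4 (-1.27, SE 0.0836), ID2, an inhibitor of basic helix-loop-helix factors (-1.17, SE 0.152), the BMP antagonist NOG (-1.15, SE 0.0867), ARHGAP22 (-1.06, SE 0.0679) and the hyaluronan synthase HAS2 (-1.04, SE 0.113) fell with TAK-981, and ADAMTS9 fell by 1.19 with ML-792 (SE 0.13). KRTAP2-3, from a family of near copies, was listed at -1.35 with TAK-981 (SE 0.135) and is uncertain.

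Of 22 hypoxia and glycolysis genes in MDA-MB-231, 0 rose and 15 fell with each compound (adjusted p = 1.49e-11 and 1.2e-11), and the calls held with an estimated correlation (adjusted p = 0.0198 for both). PDK1 fell by 0.79 with TAK-981, BNIP3 by 0.62, PFKFB4 by 0.51 and lactate dehydrogenase LDHA by 0.29. Of 24 NF-kB and inflammation genes, 16 rose and 1 fell with TAK-981 and 15 and 1 with ML-792 (adjusted p = 1.15e-10 and 4.54e-07; adjusted p = 0.383 and 0.464 with an estimated correlation). IER3 rose by 0.86 and ICAM1, an adhesion molecule, by 0.85 with TAK-981, and IL6 rose by 1.04. Of 34 replication genes, 2 rose with each compound and 18 and 17 fell (adjusted p = 1.99e-06 and 2.65e-06; adjusted p = 0.11 with an estimated correlation for both). MCM5 fell by 0.38 and MCM3 by 0.25 with TAK-981, while RRM2 rose by 0.28. Adjusted over the list alone, 17 and 16 hypoxia genes and 24 and 22 replication genes fell.

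For MHC class I presentation in MDA-MB-231, 12 of 22 rose with TAK-981 and 7 with ML-792, and 0 fell (adjusted p = 2.83e-07 and 0.0153; adjusted p = 0.161 and 0.472 with an estimated correlation), including B2M at 0.21 and IRF1 at 0.38 with TAK-981. Of 42 interferon-stimulated genes, 15 rose and 4 fell with each compound (adjusted p = 0.00277 and 0.00237; adjusted p = 0.383 and 0.373 with an estimated correlation), with SAMD9L at 1.03 and PARP14 at 0.46 with TAK-981. ATF4 and CHOP stress genes (10 rose and 1 fell of 24, adjusted p = 0.00149; adjusted p = 0.597 with an estimated correlation) and the unfolded protein response (7 rose and 0 fell of 20, adjusted p = 0.0452; adjusted p = 0.536 with an estimated correlation) were called upward with TAK-981. With ML-792 neither was called (2 rose and 1 fell, adjusted p = 0.539, and 4 rose and 0 fell, adjusted p = 0.409). NRF2 and antioxidant genes were called upward with ML-792 (7 rose and 2 fell of 20, adjusted p = 0.0345; adjusted p = 0.262 with an estimated correlation) and not with TAK-981 (7 rose and 1 fell, adjusted p = 0.0628). Epithelial markers were called downward with ML-792 (2 rose and 6 fell of 13, adjusted p = 0.0482; adjusted p = 0.58 with an estimated correlation), with a median of -0.224 but a mean of 0.003. With TAK-981 the keratin genes KRT19 (-0.60) and KRT8 (-0.25) fell and the list was not called (adjusted p = 0.0607).

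Compared directly, TAK-981 and ML-792 given at the same dose and time differed in 7 genes in HCT116, 1 in Colo205 and 3 in MDA-MB-231. In HCT116 all 7 were higher with TAK-981, by a median of 0.886, and 2 of them by 2-fold or more (largest 9.59). Of the 6 that met the limits of the naming rule there, 5 had predicted or clone names and were skipped. NR4A2, a nuclear receptor induced by many stimuli, was higher with TAK-981 in HCT116 by 0.61 (SE 0.0964, adjusted p = 0.0372), at 99.1 ± 7.51 against 65.0 ± 6.69 CPM (SD, n = 3). In MDA-MB-231 NENF was higher with TAK-981 by 0.43 (SE 0.0595, adjusted p = 0.0276) and PPP1R14B by 0.30 (SE 0.0479, adjusted p = 0.0497). The gene called in Colo205 was LOC642852 (0.85, adjusted p = 0.032), and the third in MDA-MB-231 was the read-through transcript NEDD8-MDP1, at 0 CPM with TAK-981 and 0.559 CPM with ML-792. NEDD8-MDP1 lay below the CPM limit of the naming rule and was named after its values were seen, and it is uncertain because it overlaps other genes. At an unadjusted p under 0.05 there were 1902, 1743 and 852 genes in HCT116, Colo205 and MDA-MB-231, and DESeq2 called 109, 26 and 9. Single libraries moved these small counts: HCT116 had 12 genes without TAK-981 replicate 3 and 20, 2 and 0 without ML-792 replicates 1, 2 and 3. Colo205 had 943 without ML-792 replicate 2 and 0 without any other treated library, and MDA-MB-231 had 1 without ML-792 replicate 3 and 0 without TAK-981 replicates 1 or 3 or ML-792 replicates 1 or 2. On the second principal component of Colo205, ML-792 replicate 2 lay at -6.2, beside the TAK-981 libraries (-21.1, -9.7 and -7.5), and the other ML-792 libraries lay at 18.8 and 20.2. Replicate 2 was the lowest on that component in each group, at -21.1 with TAK-981 and at -4.1 in DMSO, against 6.9 and 2.5 for the other DMSO libraries.

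The NR4A2 call was lost without TAK-981 replicate 1 (adjusted p = 0.061), 2 (0.0507) or 3 (0.0572) and without ML-792 replicate 2 (0.386) or 3 (0.334). The NENF and PPP1R14B calls were lost without any 1 of the 6 treated libraries, with adjusted p from 0.0648 to 0.363 for NENF and from 0.0648 to 0.508 for PPP1R14B. In these fits, each with fewer samples, the differences ran from 0.523 to 0.679 for NR4A2, 0.404 to 0.454 for NENF and 0.272 to 0.346 for PPP1R14B. In Colo205, where libraries with the same replicate number deviated together, the fit with the replicate number as a block gave 624 genes between the compounds. In MDA-MB-231, where 6 of 9 such pairs did, it gave 28. A p that missed the threshold did not show that the compounds acted alike. The 95% interval of the difference lay within 2-fold for 95.4%, 94.8% and 97.2% of the genes called with either compound in HCT116, Colo205 and MDA-MB-231. Among the genes that changed 2-fold or more with either compound, the interval lay within 2-fold for 61.8%, 64.9% and 62.1%.

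The log2 fold changes of the compounds correlated across genes with r = 0.619 in HCT116, 0.903 in Colo205 and 0.832 in MDA-MB-231, where genes are not independent replicates. Simulated unchanged groups set against a shared simulated DMSO group gave r = 0.503, 0.493 and 0.495. The real deviations of the 3 DMSO libraries are not part of these values. The covariance was 0.0809, 0.3 and 0.0987 against simulated values of 0.0213, 0.0217 and 0.016. Genes that rose with both compounds numbered 672, 2136 and 1175, where independent lists would share 67.1, 531.1 and 172.9. Genes that fell with both numbered 456, 2122 and 1033, against 51.6, 531.4 and 146.6. Only 3 genes in HCT116 and 0 in the other lines were called in opposite directions. The simulated unchanged groups shared a mean of 0.1, 0.2 and 0.2 called genes. Part of the excess may come from the shared controls, which were too few to split.

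**Figure D3:**
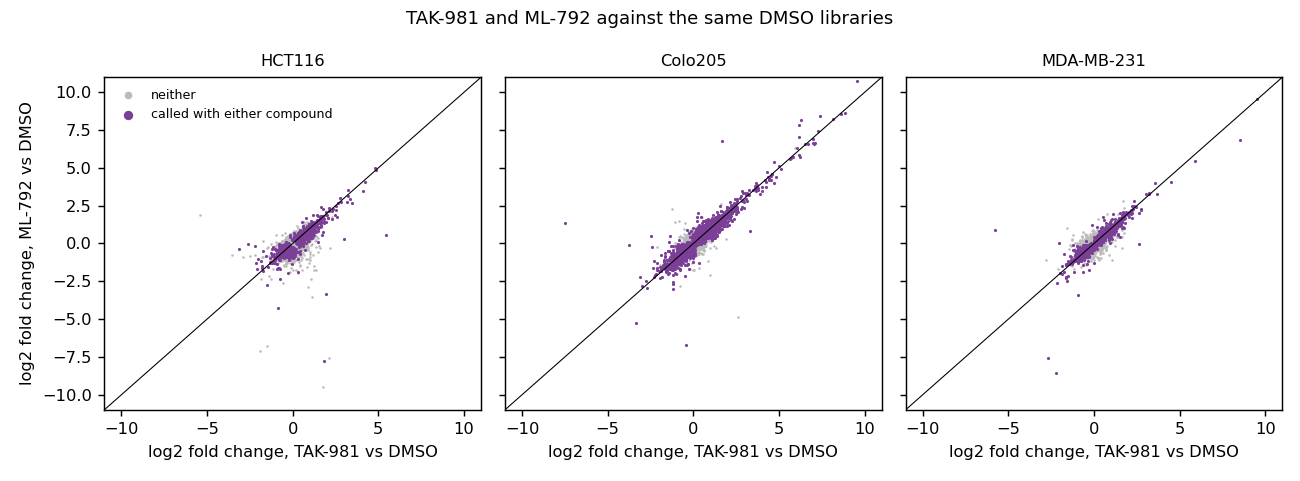
Log2 fold change with ML-792 against that with TAK-981 for each gene in HCT116, Colo205 and MDA-MB-231, both relative to the same 3 DMSO libraries (purple, called with either compound; grey, with neither; line, equal change). The values correlated across genes with r = 0.619, 0.903 and 0.832, and a few called genes lie far from the line.

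Gene lists were also called between the compounds with the preset correlation, and 0 in each line with an estimated correlation, so no difference of a list is established. Of the members of the lists that were called without a block, 0 were called over all genes in edgeR, 3 to 17 per list had an unadjusted p under 0.05, and DESeq2 called 1 ATF4 and CHOP stress gene in Colo205 and 1 in MDA-MB-231. In MDA-MB-231 MHC class I presentation (adjusted p = 3.31e-10; adjusted p = 0.109 with an estimated correlation), ATF4 and CHOP stress genes (4.34e-09; adjusted p = 0.464 with an estimated correlation), NF-kB genes (3.2e-05; adjusted p = 0.517 with an estimated correlation) and the unfolded protein response (0.00607; adjusted p = 0.464 with an estimated correlation) were higher with TAK-981. In Colo205 ATF4 and CHOP stress genes were higher with TAK-981 (adjusted p = 2.36e-07; adjusted p = 0.442 with an estimated correlation), by a median of 0.25, and adjusted over the list alone 12 were higher and 2 lower. Heat shock (0.000459), cholesterol (0.000265), NRF2 (0.00237) and unfolded protein response genes (0.0281) were lower with TAK-981 in Colo205, with adjusted p = 0.504, 0.575, 0.509 and 0.602 with an estimated correlation. With the replicate number as a block, NF-kB genes were called higher as well in Colo205 (adjusted p = 0.0122, against 0.0602 without the block; adjusted p = 0.589 with an estimated correlation and no block). In HCT116 cholesterol genes (adjusted p = 0.00022; adjusted p = 0.388 with an estimated correlation) and NRF2 genes (0.00518; adjusted p = 0.175 with an estimated correlation) were lower with TAK-981.

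Across the human lines, 117 genes rose and 42 fell in each of the 4 lines with TAK-981, among 11534 genes tested in all of them. Independent lists would share 5.8 and 4.93 genes. C20orf112 rose by 0.96 in THP-1, 2.31 in HCT116, 0.95 in Colo205 and 1.61 in MDA-MB-231 (SE 0.0707, 0.106, 0.0856 and 0.0822). The transcription factor KLF11 rose by 1.18, 1.48, 1.98 and 0.45 in the same order, and ATF7IP, a partner of the histone methyltransferase SETDB1, by 1.503, 1.496, 1.297 and 0.58. The arrestin-like gene ARRDC3 rose by 2.48, 0.76, 0.79 and 0.74, ASMTL by 1.46, 2.82, 0.95 and 0.72, and the cyclin gene CCNG2 by 1.98, 0.64, 1.22 and 0.57. FAM83D, ZNF84, C9orf3 and TRIM59 completed the first 10, with rises from 0.26 (FAM83D in MDA-MB-231) to 1.95 (C9orf3 in Colo205). Outside THP-1, the target genes UBA2 and SAE1 lay between -0.19 and 0.06 with either compound.

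The size of the TAK-981 effect differed between human lines for 10026 of 17363 genes (interaction F-test in edgeR). In the fits of each line, 1789 of the 11534 genes tested in all 4 were called in opposite directions in different lines. HDGF, a nuclear growth factor, had log2 fold changes of -2.31 in THP-1, 0.05 in HCT116, 0.08 in Colo205 and 0.14 in MDA-MB-231. CALR stood at -2.10, 0.30, 0.47 and 0.18, and CRTAP at -2.17, -0.15, -0.23 and 0.04. The cyclin-dependent kinase CDK4 stood at -1.89, 0.06, -0.37 and 0.00, FKBP1A at -2.03, 0.02, 0.03 and 0.30, TAGLN2 at -2.04, 0.01, -0.12 and -0.15, and FTL at -1.92, 0.28, 0.27 and 0.25. PHLDA1 stood at 2.97, 0.17, -0.46 and -0.11. The lipid droplet protein PLIN2 stood at 1.56, -0.17, 3.25 and 0.40, and NSMF at 0.13, 0.02, 3.47 and -0.09. The number of genes was 3522 without THP-1, and 9684, 8914 and 9113 without HCT116, Colo205 and MDA-MB-231.

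Gene lists differed between human lines as well, given as the median over the list of the difference in log2 fold change of each gene. Interferon-stimulated genes rose more in THP-1 than in HCT116, by a median of 1.64, than in Colo205 (1.30) and than in MDA-MB-231 (1.30), with adjusted p = 0.000403, 0.000129 and 8.75e-05 with an estimated correlation. Mitosis genes were lower in THP-1 than in HCT116 by a median of -0.70 (adjusted p = 0.00291 with an estimated correlation) and than in Colo205 by -0.77 (adjusted p = 0.000323 with an estimated correlation). They were higher in HCT116 and Colo205 than in MDA-MB-231, by 0.38 and 0.45 (adjusted p = 8.75e-05 and 0.00025 with an estimated correlation). The response of hypoxia and glycolysis genes was lower in MDA-MB-231 than in HCT116 and Colo205, by medians of 0.23 and 0.37 (adjusted p = 0.00123 and 0.0057 with an estimated correlation). The THP-1 values among these come from the libraries with the raised mitochondrial share of 15.5 ± 1.75%, and the list test was not matched on the level of expression.

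In the mouse lines TAK-981 raised 578 genes and lowered 559 in CT26 (12148 tested), 2245 and 2238 in MC38 (12684), 3089 and 3089 in B16F10 (12544) and 1104 and 1060 in A20 (11731). Changes of 2-fold or more numbered 71 rises and 22 falls in CT26, 342 and 104 in MC38, 536 and 218 in B16F10 and 150 and 72 in A20. The median called change was 0.332, 0.339, 0.397 and 0.375. The files did not pair the mouse identifiers with gene names, so gene lists were not tested. Without 1 library, the CT26 total of 1137 genes fell to 630 (DMSO replicate 4), 568 (DMSO replicate 5) and 529 (TAK-981 replicate 3), and the A20 total of 2164 to 1376 (DMSO replicate 5), 1194, 1327 and 1252 (TAK-981 replicates 1, 2 and 3).

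In all 4 mouse lines 62 genes rose and 68 fell among 9788 tested in each, where independent lists would share 1.3 and 1.63. ENSMUSG00000037613 rose by 3.25 in CT26, 4.93 in MC38, 5.13 in B16F10 and 7.09 in A20 (SE 0.0607, 0.0679, 0.358 and 0.366), and in A20 by 7.77 without DMSO replicate 4. ENSMUSG00000010751 rose by 2.62, 4.72, 2.62 and 2.54 (SE 0.0806, 0.069, 0.13 and 0.157). ENSMUSG00000022346 fell by 0.46, 0.57, 1.08 and 0.57 (SE 0.0532, 0.0649, 0.0678 and 0.0873), and ENSMUSG00000023942 fell by 0.33, 0.72, 0.75 and 0.58 (SE 0.05, 0.052, 0.0839 and 0.0697). The effect of TAK-981 differed between mouse lines for 5184 of 15332 genes. Leaving 1 library out of every group gave 3452 genes that differed without TAK-981 replicate 1 and DMSO replicate 4 of each line, and 2887 without TAK-981 replicate 2 and DMSO replicate 5. In the fits of each line 648 of the 9788 genes were called in opposite directions.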

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

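The tests of mitochondrial reads, of the spread between replicates, of low counts, of RLE scaling, of the replicate block and of the intervals were chosen after their results were seen, as were the fits without 1 human line and without mitochondrial genes. The parting of THP-1 from the other comparisons in the test of low counts, and its 95% bounds, were also set after the values were seen.

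The response to TAK-981 differed between human lines for 10026 genes and between mouse lines for 5184 genes by the interaction test. Between pairs of human lines the tests gave 8190 genes for THP-1 and HCT116, 7578 for THP-1 and Colo205 and 7852 for THP-1 and MDA-MB-231. They gave 2311 for HCT116 and Colo205, 1191 for HCT116 and MDA-MB-231 and 1951 for Colo205 and MDA-MB-231. Between mouse lines they gave 1132 for CT26 and MC38, 2863 for CT26 and B16F10, 1070 for CT26 and A20, 3223 for MC38 and B16F10, 2125 for MC38 and A20 and 2950 for B16F10 and A20.

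The genes with the smallest adjusted p for a difference between human lines had ranges between the highest and lowest log2 fold change of 3.56 for NSMF, 3.43 for PHLDA1, 3.41 for PLIN2, 2.57 for CALR, 2.45 for HDGF, 2.33 for FKBP1A, 2.22 for CRTAP, 2.19 for FTL, 2.05 for TAGLN2 and 1.96 for CDK4.

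Gene lists whose response differed between lines, also with an estimated correlation, gave these medians, over the genes of the list, of the difference in log2 fold change between the lines. Interferon-stimulated genes were higher in THP-1 by 1.64 than in HCT116, by 1.30 than in Colo205 and by 1.30 than in MDA-MB-231. Mitosis genes differed by -0.70 between THP-1 and HCT116, by -0.77 between THP-1 and Colo205, by 0.38 between HCT116 and MDA-MB-231 and by 0.45 between Colo205 and MDA-MB-231. The p53 targets were higher in THP-1 than in Colo205 by 0.64 and than in MDA-MB-231 by 0.29, and higher in HCT116 than in MDA-MB-231 by 0.17. Hypoxia and glycolysis genes were higher in HCT116 and Colo205 than in MDA-MB-231 by 0.23 and 0.37. Ribosome biogenesis genes differed by -0.28 between Colo205 and MDA-MB-231.

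THP-1 had the most calls of the human lines, and its TAK-981 libraries held 15.5 ± 1.75% mitochondrial counts against 7.38 ± 0.215% in DMSO (SD, n = 3). Without the mitochondrial genes 10085 genes were called in THP-1, against 10074 with them, but that setting changed 0 of 813 results and so tested little, and an effect of RNA quality stays open. Removing a smooth trend on transcript length and GC content left 2416 calls of 2-fold or more, against 2613 before it among the same genes (91.6% of those tested had a value) and 528 after it in Colo205, the next line, so that trend was not the whole cause. The common biological coefficient of variation was 0.072 in THP-1 and 0.0417 in MDA-MB-231, the lowest, which argues against a smaller spread as the cause. A difference of cell type stays open and may underlie the number, but only 1 myeloid line was measured and this was not tested.

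Calls of 2-fold or more were mostly rises in all 11 comparisons with DMSO, from 57.9% in THP-1 to 79.4% with TAK-981 in HCT116. In THP-1, low counts, taken here only as a mean under 10 CPM, may account for this. Among genes with a mean of at least 10 CPM, 36.7% were rises (525 of 1430, exact 95% interval 34.2 to 39.3%). In the other comparisons the lower bound lay over 50% in 10 of 10, also with the geometric mean of both groups, which treats rises and falls alike. The bounds lay close to it in MC38 (51.9 and 50.5%) and B16F10 (51.7 and 51.5%). All these intervals treat the called genes as independent, which they are not, and measure no spread between samples. Rises thus remained the majority above the limit outside THP-1, but the intervals cannot decide whether low counts were the whole cause there. A mean of at least 10 CPM in DMSO alone, which leaves out genes that rose from low levels, gave over 50% in 8 of 11, with 48.5% in MC38, 42.9% in B16F10 and 25.8% in THP-1. RLE scaling moved the share by at most 1.3 percentage points but changed only 2 of 839 results, so the scaling stays open, as does an effect of the inhibitors, which was not tested.

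Only 1 gene differed between TAK-981 and ML-792 in Colo205, although 5092 and 5915 were called against DMSO. With the replicate number as a block 624 genes were called, so spread shared by libraries of the same number may have hidden differences. The 95% interval of the difference lay within 2-fold for 94.8% of the genes called with either compound but for 64.9% of those that changed 2-fold, and most called changes were themselves smaller, so imprecise differences stay open. ML-792 replicate 2 also counts: without it 943 genes were called. Replicate 2 was the lowest on the second principal component in each group (-4.1 in DMSO, -21.1 with TAK-981 and -6.2 with ML-792), so the spread shared by the number may also account for its place near the TAK-981 libraries, which 3 groups are too few to settle.

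For each comparison of 3 libraries with 3, 10 splits are too few for a share under 0.05. The real split alone gave as many calls (1 of 10) in each comparison but that of the compounds in Colo205, where 3 of 10 did, with 1 real call and 3 as the highest other. The highest other count was 0 for THP-1 (real 10074, of them 2924 of 2-fold or more), MC38 (4483 and 446), B16F10 (6178 and 754), A20 (2164 and 222), and in MDA-MB-231 for TAK-981 (2818 and 184) and ML-792 (3164 and 181). It was 1 for HCT116 with TAK-981 (2098 and 175), with ML-792 (1643 and 143) and between the compounds (7), and for CT26 (1137 and 93). It was 2 between the compounds in MDA-MB-231 (3). In Colo205, where the numbers pair the libraries, splits that part as many pairs gave at most 0 for TAK-981 (5092 and 608) and ML-792 (5915 and 677), and at most 3 between the compounds.

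With the labels shuffled within every line, the real labels alone gave as many genes called alike in all human lines (159, 1 of 100 draws, highest other 0) and in all mouse lines (130, 1 of 100, highest other 0). As other splits called at most 1 gene in each line, the shuffled counts could hardly rise above 0, so this excludes only that the labels were arbitrary and says nothing of sharing beyond the calls of each line. For the differences between lines, the real labels alone gave as many genes in human lines (10026, 1 of 40 draws, highest other 7470). The same held in mouse lines (5184, 1 of 40, highest other 3760). Shuffling within each line does not make the effect of TAK-981 equal across lines. These draws therefore exclude only that the labels were arbitrary and do not test whether the lines differ beyond chance. The lists called (63, 1 of 100 draws) lay only just above the highest other draw (62), so this count barely parts real from shuffled labels. The shuffles are not free of the treatment, since a split of 2 against 1 keeps part of it and some draws keep the real labels of a line: 98 of the other 99 draws called at least 10 lists (median 40).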

How the results depend on the processing

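Of 409 alternatives to the 42 counts and correlations that answer a comparison, 286 were counted as within 1.5 times and 123 as moved. The correlations between the compounds at 10 CPM were counted as moved without that rule, although each stayed within 1.5 times. Over 902 results, gene by gene included, 11040 of 11534 alternatives kept their direction and side of the threshold, 393 lost the call and 67 gained one. Another 34 changed sign with no call in either fit, and 0 changed sign with a call. The fit of log2(FPKM + 1), the fit without mitochondrial genes, the 10 CPM limits on 2-fold calls and the differences between human lines without 1 line were chosen after seeing the data. All settings fixed beforehand were run. Unless given, the cause was not tested. Depth limits the precision of genes with few counts. Most 2-fold calls in each comparison lay below a mean of 10 CPM over the line, but how many of them had few counts was not measured.

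With DESeq2, 2-fold calls were 116 with TAK-981 in HCT116 and 116 with ML-792 in MDA-MB-231, and 109, 26 and 9 genes differed between the compounds in HCT116, Colo205 and MDA-MB-231. In a fit of the 2 groups alone these were 0, 2 and 16, and TAK-981 called 1265 genes in HCT116. In one fit over all lines they were 165, 17 and 0, and 3183 genes were called with TAK-981 in HCT116, 1645 in MDA-MB-231 and 1819 there with ML-792. Without the low-count filter they were 113, 49 and 28, and 2-fold calls were 163 in CT26 and 724 in MC38. RLE scaling gave 1 and leaving out mitochondrial genes 5 in MDA-MB-231. Without THP-1, 3522 genes differed between human lines. Fewer lines alone did not give that count, as 9684, 8914 and 9113 differed without HCT116, Colo205 and MDA-MB-231.

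The pseudocount shrinks low genes by construction: with log2(FPKM + 1), 2-fold calls were 1556 in THP-1, 51 and 45 in HCT116 (TAK-981 and ML-792), 178 and 178 in Colo205, 43 and 43 in MDA-MB-231, 27 in CT26, 146 in MC38, 293 in B16F10 and 79 in A20. CT26 had 696 calls, and 3 and 0 genes differed between the compounds in HCT116 and Colo205. With a mean of at least 10 CPM over the line, which leaves fewer genes, the 2-fold calls were in the same order 1430, 50 and 44, 152 and 167, 39 and 37, 16, 121, 237 and 58. With that mean over the DMSO libraries they were 1300, 40 and 36, 124 and 138, 27 and 28, 16, 99, 205 and 48. With the geometric mean of both groups they were 1363, 48 and 40, 139 and 154, 35 and 34, 15, 113, 223 and 55. Correlations between the compounds at 10 CPM were 0.799, 0.942 and 0.949 in HCT116, Colo205 and MDA-MB-231. Simulated unchanged groups against a shared simulated DMSO group gave 0.499, 0.498 and 0.492.

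With the replicate number as a block, 624 genes differed between the compounds in Colo205 and 28 in MDA-MB-231. In Colo205 it moved no other count by over 1.5 times. Only 3 of 9 same-number pairs in HCT116 (correlations -0.261 to 0.234) and 6 of 9 in MDA-MB-231 (-0.104 to 0.35) were over 0.1. In MDA-MB-231 these include the 3 pairs of DMSO with TAK-981, so the numbers may pair part of its libraries. In neither line did every library correlate best with its own number. The block changed 3 list calls in these lines. In MDA-MB-231 the epithelial markers with ML-792 were no longer called (adjusted p = 0.0564, against 0.0482 without the block), and ribosome biogenesis genes were called higher with TAK-981 than with ML-792 (0.0078 against 0.0577). In HCT116 the mesenchymal markers were called with TAK-981 (0.045 against 0.0677). Without the block, neither these markers nor those ribosome biogenesis genes were called with an estimated correlation.

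With an estimated correlation, lists called were 0 in THP-1, 1 and 1 in HCT116 (TAK-981 and ML-792), 0 and 0 in Colo205, 1 and 1 in MDA-MB-231, and 0 between the compounds in each line. That test has few degrees of freedom in each line, fewest in THP-1, so these counts do not rank the lines. With fry, which tests another hypothesis, they were 17 in THP-1, 10 and 15 in Colo205, 11 with TAK-981 in MDA-MB-231, and 1, 0 and 2 between the compounds.

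Leaving out each library in turn gave 1281 to 1903 calls with TAK-981 in HCT116 (1374 without DMSO replicate 1, 1281 without DMSO replicate 2). With ML-792 there it gave 768 to 1542 (944 and 1032 without DMSO replicates 2 and 3; 1064, 768 and 874 without ML-792 replicates 1, 2 and 3). Between the compounds it gave 0 to 20 in HCT116 (12 without TAK-981 replicate 3; 20, 2 and 0 without ML-792 replicates 1, 2 and 3), 0 to 943 in Colo205 (943 without ML-792 replicate 2, 0 without any other) and 0 to 2 in MDA-MB-231 (1 without ML-792 replicate 3, 0 without TAK-981 replicates 1 and 3 and ML-792 replicates 1 and 2). It gave 529 to 1333 in CT26 (630 and 568 without DMSO replicates 4 and 5, 529 without TAK-981 replicate 3) and 1194 to 2706 in A20 (1376 without DMSO replicate 5; 1194, 1327 and 1252 without TAK-981 replicates 1, 2 and 3). Leaving 1 library out of every group at once gave 2887 to 3646 differences between mouse lines (3452 without TAK-981 replicate 1 and DMSO replicate 4 of each line, 2887 without TAK-981 replicate 2 and DMSO replicate 5). Each of these fits has fewer samples.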

Other observations

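The genes of the next paragraph were chosen after their values were seen, and so was the zinc-finger test. The test of neighbouring genes was written before its result.

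Of the 117 genes that rose and 42 that fell in all 4 human lines with TAK-981, these are single examples and not a tested group. RHOB, a small GTPase, rose by 1.63 in THP-1, 0.57 in HCT116, 0.72 in Colo205 and 0.62 in MDA-MB-231 (SE 0.0715, 0.0787, 0.0913 and 0.0809). JUN, a subunit of the AP-1 transcription factor, rose by 1.05, 0.80, 0.96 and 0.41 in the same order (SE 0.0904, 0.121, 0.0482 and 0.0476), and PMAIP1, which encodes the pro-apoptotic protein NOXA, by 0.78, 0.42, 0.38 and 0.62 (SE 0.0975, 0.0729, 0.0752 and 0.0352). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 5.33, 0.79, 4.61 and 1.70 (SE 0.478, 0.113, 0.508 and 0.138). UNG, the uracil-DNA glycosylase of base excision repair, fell by 0.63, 0.57, 0.36 and 0.19 (SE 0.0683, 0.0628, 0.0516 and 0.0382), and LRP8, a receptor of the LDL receptor family, fell by 0.43, 0.46, 0.91 and 0.26 (SE 0.0639, 0.0675, 0.064 and 0.0485).

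Fold changes of TAK-981 correlated weakly between human lines across genes (r from 0.067 for THP-1 and HCT116 to 0.278 for HCT116 and Colo205) and between mouse lines from 0.251 for CT26 and A20 to 0.416 for CT26 and MC38. Genes are not independent replicates, and the lines shared no control libraries. Rank correlations of the fold changes with transcript length were 0.182 in THP-1, -0.27 in HCT116, 0.05 in Colo205 and 0.096 in MDA-MB-231. Whether these trends lowered the correlations between the human lines was not tested.

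The zinc-finger genes ZNF84, ZNF699, ZNF45 and ZSCAN31 were among the rises, and it was tested whether genes named ZNF, ZSCAN, ZKSCAN or ZFP rose as a class. They did by camera in 4 of 4 human lines, with adjusted p = 0.0149 in THP-1, 0.0236 in HCT116, 0.0312 in Colo205 and 0.0236 in MDA-MB-231 with an estimated correlation. These values were adjusted over the 4 lines alone. The fixed lists were adjusted over all lists and comparisons, a heavier correction, so the class cannot be called sturdier than those lists. In THP-1 352 of 500 rose, in libraries in which the mitochondrial genes took 15.5 ± 1.75% of counts against 7.38 ± 0.215% in DMSO (SD, n = 3). In HCT116 82 of 429 rose, in Colo205 152 of 456 and in MDA-MB-231 115 of 502. Those are shares of 70.4, 19.1, 33.3 and 22.9%, where 35.5, 7.67, 17.9 and 10.6% of all genes rose. Reads shared between these similar genes were not excluded, and why the class rose was not tested.

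Since the nearby genes ASMTL and CSF2RA both rose in HCT116, it was tested whether adjacent genes change together. Whether they form such an adjacent pair themselves was not examined. The rank correlation of the fold changes of adjacent genes was 0.089 in THP-1, 0.188 in HCT116, 0.111 in Colo205 and 0.115 in MDA-MB-231, above the highest of 1000 shuffled gene orders (0.037, 0.025, 0.026 and 0.034) in 4 of 4 lines. The p of 0.001 in each is the smallest that these shuffles can give. Regional control of expression may contribute, but overlapping reads counted without strand, families of similar neighbours and shared GC content were not excluded.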
